A study of Mus musculus with 8 samples.

How the data were processed

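Spatial gene expression was measured in mouse kidney with the 10x Genomics Visium assay for formalin-fixed, paraffin-embedded tissue, in which pairs of probes for each gene are ligated on the tissue and captured on an array of barcoded spots. Each of 8 mice gave 1 section of 5 µm. One mouse had sham surgery, 3 had unilateral ureteral obstruction (UUO) and received vehicle, and 4 had UUO and received CH6824025, named in the series title as an inhibitor of the collagen receptor DDR1, at 200 mg/kg by mouth for 8 days. Per the labels, UUO mice were analysed on day 7 after surgery. Sections are named by group and animal number.

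The deposited matrices hold raw UMI counts per gene and spot, with no normalization; the UMI (unique molecular identifier) counts were made by the authors with Space Ranger, whose version in the file headers is 1.3.1, on the mm10 assembly named in the labels. The values were checked to be whole numbers, and the number of matrix columns was checked to equal the number of spots over tissue. The deposited position files give a value of 1 or 0 for tissue under each of 4992 spots, together with array and pixel coordinates, and the deposited scale factor files give image scales, which are other units than counts. Tissue images were not used here. The matrices list 19465 genes by Ensembl identifier and symbol, of which 22 symbols are used by more than 1 identifier. Gene coordinates came from the RefSeq annotation of GRCm38.p6, the same assembly, matched by symbol.

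Spots over tissue with at least 500 UMIs were kept, which removed 0 to 3 spots per section. Spots are not replicates, so counts were summed per section, and each section was 1 sample in every test between groups. Library totals ranged from 67036817 to 155671493 UMIs. A count of 0 allows up to 3 counts, which is 0.0193 to 0.0448 CPM (counts scaled to a common section total, as edgeR gives them) in the 8 sections. Intervals and limits of this kind cover counting error only.

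Gene tests used edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default filter on low counts by group, quasi-likelihood fits, and Benjamini-Hochberg adjustment with a threshold of 0.05. CH6824025 was compared with vehicle in the 7 UUO sections. UUO vehicle was compared with sham in a fit of all 8 sections with a coefficient per group, in which the single sham section is assumed to vary like the UUO sections. The standard error printed beside an edgeR log2 fold change is the fitted log2 fold change divided by the square root of the F statistic. All tests were 2-sided. DESeq2 1.42.0 and limma 3.58.1 served as other tools. Group means of CPM are unscaled, so their ratio can differ from the fold change fitted after TMM scaling. For genes of UUO vehicle against sham given both ways, the CPM ratio lay above the fitted fold change throughout. Rises read from CPM means are larger there than the fitted ones, and falls are smaller.

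The gene lists were fixed before the data were examined, as were the groups, the tests, the rule for named genes and the other settings listed last. There were 15 lists of processes, namely interstitial matrix and myofibroblast, basement membrane, collagen receptors, TGF-beta signalling and targets, chemokines and cytokines, antigen presentation by class II molecules, interferon response, complement, tubule injury, cell cycle, immediate early and heat shock, fatty acid oxidation, oxidative phosphorylation, NRF2 and antioxidant, and xenobiotic metabolism. There were 18 lists of cell type or region markers, namely macrophage and monocyte, T and NK cell, B and plasma cell, neutrophil, proximal tubule, thick ascending limb, distal convoluted and connecting tubule, collecting duct principal cell, collecting duct intercalated cell, inner medulla and thin limb, pelvis urothelium, podocyte and glomerulus, endothelium, smooth muscle and pericyte, adipocyte, erythroid, skeletal muscle, and adrenal cortex. Some genes stand in more than 1 list, among them Ccn2, Spp1, Mrc1 and the C1q genes. Lists with at least 5 tested genes were compared by camera with a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. The percent of UMIs that a list took in each section was compared by an exact permutation test. With 3 sections against 4 there are 35 splits, and the smallest 2-sided p is 0.0571.

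The named genes of CH6824025 against vehicle were Ddr1, Ddr2 and the 10 genes per direction with the smallest p past the threshold, or the 5 smallest where fewer passed, named as not past it. Those of UUO vehicle against sham were Ddr1, Ddr2 and the 12 per direction with the largest change past the threshold and a mean of at least 50 CPM in the higher group. Up to 4 members per list with the smallest p could be named as well. Some genes that this rule names are not reported here.

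Regions came from clusters of spots made with scanpy 1.11.5 and leidenalg 0.10.2 in Python 3.11.15 (NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3), from 2000 variable genes, leaving out the genes of the process and immune lists, centred per section, with 30 principal components, 15 neighbours and a resolution of 0.8. A cluster took the name of the marker list with the most members among its 25 leading genes, or stayed unnamed. Regions with at least 50 spots in every section were tested for genes. The planned interaction of region and treatment was for the 2 largest named regions, which were the proximal tubule and the inner medulla. The inner medulla failed the check of its markers, so the distal convoluted and connecting tubule took its place. For spots with Ddr1, each spot of at least 24000 UMIs was thinned to that number. Spots below it were left out, 166 to 1070 per UUO section, most of them in CH6824025 22. The log2 ratio of a list between spots with and without a Ddr1 UMI was tested over the 7 UUO sections by exact sign flips, whose smallest 2-sided p is 0.0156. For the genes changed by UUO, 40 data sets were simulated with no treatment effect and the same vehicle libraries, since both comparisons share the vehicle sections.

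A gene was counted as lost from a section when it averaged at least 10 CPM in the reference sections and lay more than 8 times below them. The reference was the UUO sections other than vehicle 18, CH6824025 22 and the section itself, so these sections were already set apart in this count. Log2 differences had 0.05 CPM added and were centred on their median over the genes of a section. Because gene loss stood out in UUO vehicle 18 and UUO CH6824025 22, further alternatives were chosen after seeing the data. These were fits without both sections, here called the 5-section fit, or the 6-section fit when sham is included; limma voom with a quality weight per section; fits that also left out the spots of cluster 6 of the marker panel, found mostly in vehicle sections; clusters made from a panel of 105 region markers standardised within each section, with 15 principal components and a resolution of 0.5 taken after 0.3, 0.5 and 0.8 had been looked at; and a split of spots at the median of Ddr1 UMIs. Panel genes were left out of counts within and between panel clusters.

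The fits were tested on simulated data in which 100 genes were changed 2-fold and another 100 were changed 4-fold, all of at least 10 CPM. The interstitial matrix list was shifted by less in the same data. The 7-section fit of 15281 genes recovered 0 of 100 at 2-fold and 0 of 100 at 4-fold. The 5-section fit of 15400 genes recovered 100 of 100 at each size, with 17 false calls. The other settings were RLE size factors, DESeq2, no filter on low counts, every spot over tissue, at least 2000 UMIs per spot, thinned spots, a fit of all 8 sections, the proximal tubule share as a covariate, other cluster settings, and leaving out each UUO section in turn. Figures were drawn with matplotlib 3.10.9.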

Results

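Gene expression was profiled across kidney sections from 1 sham mouse, 3 UUO mice given vehicle (animals 16, 18 and 19) and 4 UUO mice given CH6824025 (animals 21 to 24). UUO blocks urine outflow from a kidney and leads to tubule injury, inflammation and fibrosis. The sham section held 2299 spots and 93993198 UMIs. The vehicle sections held 1974, 2150 and 2050 spots with 102874576, 107295404 and 95481506 UMIs. The CH6824025 sections held 2025, 2218, 2320 and 2420 spots with 87539342, 67036817, 133773306 and 155671493 UMIs, in the order of the animal numbers. Median UMIs per spot were 34197 in sham, 38495 to 46470.5 in the vehicle sections and 24628.5 to 54592 in the CH6824025 sections, lowest in animal 22. The 10 most abundant genes took 7.23% to 8.73% of the UMIs of a section.

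Vehicle 18 and CH6824025 22 lacked signal from a shared set of genes that the other UUO sections expressed well. Genes with fewer UMIs in both than in the other UUO sections included Rab5a, a small GTPase of early endosomes, Pik3r1, a regulatory subunit of phosphoinositide 3-kinase, and Hprt, a purine salvage enzyme. These 3 examples were chosen after their values were seen. Rab5a gave 0 UMIs in CH6824025 22, which allows up to 0.0448 CPM, and 568 in vehicle 18, against 3218 to 5453 in the other 5 UUO sections and 2837 in sham. Hprt gave 11 and 1350 UMIs in these sections against 10899 to 21433 in the other UUO sections. Of 10473 genes averaging at least 10 CPM in the other 5 UUO sections, 2117 (20.2%) lay more than 8 times lower in CH6824025 22 and 301 (2.87%) in vehicle 18, after centring on each section's median. In each of the other UUO sections at most 1 such gene was found, and in sham 72 (0.687%). The lists shared 296 genes, where 60.8 would be shared by independent draws. CH6824025 22 also had the fewest detected genes, 15829 against 18433 to 18668 in the other CH6824025 sections.

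**Figure D1:**
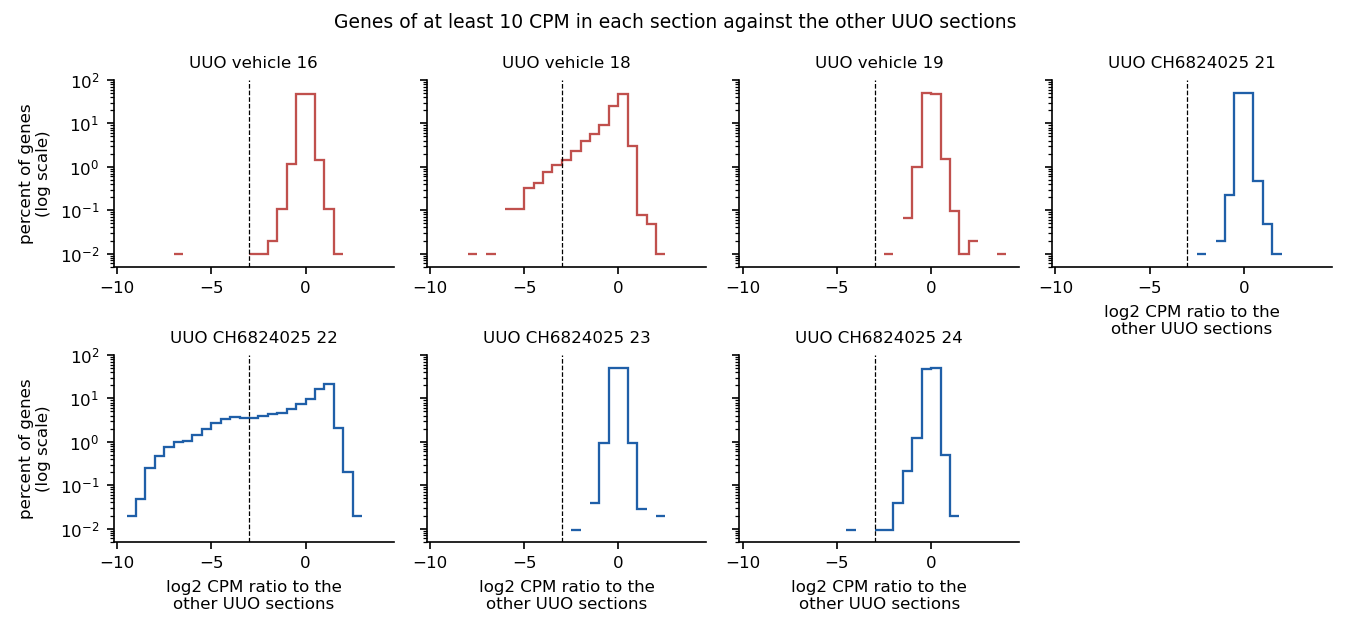
Distribution over genes of the log2 ratio of each UUO section's CPM to the UUO sections other than itself, vehicle 18 and CH6824025 22 (x axis), as percent of genes on a log scale (y axis), with a dashed line at 8-fold lower. Ratios are centred on the median of each section. CH6824025 22 has 20.2% and vehicle 18 has 2.87% of genes beyond the line.

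UUO vehicle against sham asks what obstruction did to the kidney. C3, the central complement component, rose from 20.1 CPM in sham to 1179 ± 253 CPM (SD, n = 3). Spp1, which encodes osteopontin, rose from 1402 to 27646 ± 2639 CPM. Clu, which encodes the secreted chaperone clusterin, rose from 168 to 4176 ± 916 CPM. Col3a1, type III collagen, rose from 153 to 2274 ± 393 CPM. Sord, sorbitol dehydrogenase, fell from 773 to 242 ± 18.0 CPM, and Cbs, cystathionine beta-synthase, fell from 211 to 82.2 ± 5.14 CPM. With edgeR, 66 of 15908 genes passed the threshold, 51 higher and 15 lower in UUO vehicle.

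The largest rises among the genes past the threshold with at least 50 CPM in this fit of 8 sections were those of Arhgap36, with a log2 fold change of 7.51 ± 0.54 (SE; edgeR adjusted p = 0.0243; Ensembl ENSMUSG00000036198, mm10 chromosome X, 49448360 to 49500244), and C3, with 5.56 ± 0.42 (adjusted p = 0.0243; ENSMUSG00000024164, chromosome 17, 57203967 to 57228136). Among those that followed were diamine oxidase Aoc1 with 4.89, the retinoic acid synthesis enzyme Aldh1a2 with 4.71, Clu with 4.33, the fibrinogen chain gene Fgb with 4.30, the cytokine signalling inhibitor Socs3 with 4.27, the hyaluronan receptor Cd44 with 4.04, Inhbb with 4.01, Spp1 with 3.99 and Col3a1 with 3.58. Only 10 lower genes met the 50 CPM minimum. Gpx6, a glutathione peroxidase, fell by 3.49 on the log2 scale, Dusp15 fell by 3.47, the transporter gene Slc22a28 fell by 2.47, Cpt1b, a carnitine palmitoyltransferase, fell by 2.43, and the carboxylesterase gene Ces1f fell by 2.25. Gnmt, Sord, Dmgdh, Cbs and Slc47a1 fell by 2.09, 1.99, 1.88, 1.67 and 1.67. Adjusted p of these named genes ranged from 0.0243 to 0.0484. Ddr1 was at 129 CPM in sham and 222 ± 23.9 in UUO vehicle, with a log2 fold change of 0.47 ± 0.26 (edgeR adjusted p = 0.524), and Ddr2 at 8.59 and 22.0 ± 14.7 CPM (1.05 ± 1.51, adjusted p = 1).

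These calls were sensitive to single sections. The edgeR count was 0 when vehicle 16, 18 or 19 or CH6824025 21, 23 or 24 was left out, where 1634 to 1917 genes had an unadjusted p under 0.05, and it was 4231 without CH6824025 22. In the 6-section fit, chosen after seeing the data, 8228 of 15843 genes passed, 4327 higher and 3901 lower, among them all 51 higher and all 15 lower genes of the fit of 8. There the matrix protease Mmp7 rose by 10.18 on the log2 scale, the injury markers Havcr1 (KIM-1) and Lcn2 (NGAL) by 7.93 ± 0.48 and 6.90 ± 0.32, and Egf, made by the thick ascending limb, fell by 3.59 (SE 0.18). Ddr1 rose by 0.40 ± 0.10 (edgeR adjusted p = 0.014) and Ddr2 by 1.52 ± 0.17 (adjusted p = 0.000341).

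Among the gene lists, interstitial matrix was higher in UUO vehicle (camera adjusted p = 2.18e-17), with all 38 measured members above 0. Col3a1 and Col1a1 passed over all genes, and 22 members passed adjusted over the list alone. Macrophage and monocyte markers were higher (1.55e-16), with C1qc, Ctss, Cd14 and Ccr2 past the gene test at 2.46, 2.69, 2.80 and 2.95 and 15 of 22 adjusted over the list alone. Tubule injury was higher (1.55e-16), with Spp1, Clu, Cd44 and Cdkn1a past the gene test and 17 of 22 adjusted over the list alone. Chemokines and cytokines (camera adjusted p = 4.41e-11, Spp1 and Cxcl1 past the gene test, 13 of 27 adjusted over the list alone) were higher too. So were TGF-beta signalling (3.75e-09, the matrix protein gene Ltbp2 at 5.52, and 10 of 18) and complement (1.6e-08, C3, C1qc and C4b, and 9 of 13). Immediate early and heat shock genes (0.000468, 6 of 13) and collagen receptors (0.000874, 3 of 11) were also higher. These 8 calls held with an estimated correlation, where their adjusted p ranged from 0.00695 to 0.0355.

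Class II antigen presentation, the cell cycle, T and NK cell markers, the interferon response and basement membrane were also higher with the preset correlation. Their adjusted p were 1.84e-05, 0.000328, 0.00061, 0.0025 and 0.0475, and these calls were lost with adjusted p = 0.0567, 0.0567, 0.0583, 0.125 and 0.11 with an estimated correlation. No member of these lists passed over all genes, and 6, 3, 1, 0 and 0 passed adjusted over the list alone. H2-Ab1, a class II chain, was at 106 CPM in sham and 474 ± 38.9 in UUO vehicle (log2 1.84 ± 0.31, edgeR adjusted p = 0.0573), and Mki67, a marker of cycling cells, at 7.45 and 42.9 ± 5.54 CPM (2.21 ± 0.48, adjusted p = 0.0844).

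Proximal tubule markers were lower (camera adjusted p = 1.31e-12), with all 25 measured members below 0, none past the gene test over all genes and 11 adjusted over the list alone. The glycine amidinotransferase gene Gatm was at 1328 CPM in sham and 332 ± 51.0 in UUO vehicle, and the transporter gene Slc7a13 at 300.0 and 47.7 ± 16.3. Fatty acid oxidation (6.68e-10; all 22 below 0, 7 adjusted over the list alone), oxidative phosphorylation (1.28e-07; all 19 below 0, 6 adjusted over the list alone), thick ascending limb (0.000198; 11 of 12 below 0, 3 adjusted over the list alone), distal convoluted and connecting tubule (0.000316; 8 of 10 below 0, 3 adjusted over the list alone) and intercalated cell markers (0.000699; all 10 below 0, 3 adjusted over the list alone) were lower as well, and these 6 calls held with an estimated correlation (adjusted p from 0.00695 to 0.0449). Acsm2, an acyl-CoA synthetase, was at 3838 CPM in sham and 1028 ± 109 in UUO vehicle (log2 -2.21 ± 0.32, edgeR adjusted p = 0.0502). Xenobiotic metabolism (0.00262), pelvis urothelium (0.00515) and adipocyte markers (0.0425) were lower with the preset correlation only, with adjusted p = 0.0911, 0.264 and 0.379 with an estimated correlation. Among the adipocyte markers, Ucp1, the uncoupling protein of brown fat, fell by 4.84 from 5.01 CPM. By share of UMIs the adipocyte list was not lower, at 0.0184% in sham and 0.0233% ± 0.00704 in UUO vehicle (SD, n = 3).

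B and plasma cell, neutrophil, NRF2, principal cell, podocyte, endothelium, smooth muscle, skeletal muscle, erythroid and inner medulla lists did not pass, with camera adjusted p from 0.11 to 0.886. The median and mean member differed in sign for the inner medulla (0.12 and -0.05), skeletal muscle (0.16 and -0.44) and erythroid lists (-0.16 and 0.14). In all, 22 lists passed with camera, 14 with an estimated correlation and 18 with fry. In the 6-section fit 20 passed, 0 of them with an estimated correlation. Adrenal cortex had fewer than 5 tested genes; it took 0.000352% of UMIs in sham and 0.000713% ± 0.000146 in UUO vehicle (SD, n = 3).

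CH6824025 against vehicle asks what the compound changed in the obstructed kidney. Over all 7 UUO sections no single gene passed with edgeR. Lists of matrix, class II and interferon genes passed camera as lower with CH6824025 and lists of tubule and mitochondrial genes as higher, all with a preset correlation. With an estimated correlation 0 lists passed, with adjusted p of at least 0.0644. Fbn2, the microfibril protein fibrillin-2, had the smallest p, at 16.5 ± 2.04 CPM in vehicle (SD, n = 3) and 3.61 ± 0.698 in CH6824025 (n = 4). Of 15377 genes, 0 passed the threshold with edgeR, 556 had an unadjusted p under 0.05 and the smallest adjusted p was 0.938, while DESeq2 called 48, 9 higher and 39 lower. Among the 5 higher genes with the smallest p, none past the threshold, were Gm9732 (log2 0.96 ± 0.20), the glyoxalase-domain gene Glod5 (0.69 ± 0.16), the lysosomal peptidase gene Dpp7 (0.96 ± 0.23) and Dmp1 (1.39 ± 0.34). The 5 lower ones were Fbn2 (-2.05 ± 0.24; ENSMUSG00000024598, mm10 chromosome 18, 58008623 to 58210572), Pcdh15 (-3.27 ± 0.51), the granzyme gene Gzmc (-2.51 ± 0.39), Prr29 (-2.24 ± 0.35) and Fcgbp (-3.95 ± 0.62).

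Ddr1, the named target, was at 222 ± 23.9 CPM in vehicle and 221 ± 10.9 in CH6824025, with a log2 fold change of 0.15 ± 0.15 (edgeR adjusted p = 1; ENSMUSG00000003534, mm10 chromosome 17, 35681567 to 35704741). Ddr2, the related collagen receptor of mesenchymal cells, was at 22.0 ± 14.7 and 18.6 ± 11.8 CPM (-0.14 ± 0.94, adjusted p = 1; ENSMUSG00000026674, chromosome 1, 169972307 to 170110836). In the 5-section fit they were at 0.18 ± 0.07 (edgeR adjusted p = 0.171) and -0.23 ± 0.11 (adjusted p = 0.237).

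In the 5-section fit, chosen after seeing the data, single genes did pass. Cyp4a14, a fatty acid omega-hydroxylase, rose from 99.6 ± 10.0 CPM (SD, n = 2) to 295 ± 36.6 (n = 3), a log2 fold change of 1.65 ± 0.11 (edgeR adjusted p = 0.00643; ENSMUSG00000028715, mm10 chromosome 4, 115486200 to 115496158). Slitrk4 rose by 1.91, the clock repressor gene Cry1 by 1.04, Ly6a, which encodes the surface protein SCA-1, by 0.97, Gm4450 by 0.92, Dpp7 by 0.83, the cytochrome c oxidase subunit gene Cox7a1 by 0.82, the monocarboxylate transporter gene Slc16a5 by 0.82, Glod5 by 0.69 and the mitochondrial gene Chchd10 by 0.67. Fbn2 fell by 1.98, the organic anion transporter gene Slco1a1 by 1.67, Atp10b by 1.13, Trp53i11 by 1.03, the phosphodiesterase gene Pde2a by 0.89, the receptor partner gene Ramp3 by 0.81, Vgll3 by 0.81 and Bok, a BCL2 family gene, by 0.77. The edgeR adjusted p of these genes ranged from 0.00643 to 0.0097.

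The 5-section fit called 1287 of 15471 genes, 698 higher and 589 lower. Voom with section quality weights over all 7 sections called 1377, 701 higher and 676 lower, and gave CH6824025 22 a weight of 0.0199 and vehicle 18 a weight of 0.185, against 2.64 to 4.37 in the others. The fits shared 547 higher and 459 lower genes.

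Of the gene lists, 11 passed in the 7 UUO sections, 6 higher and 5 lower with CH6824025, and 0 of them with an estimated correlation or with fry. Without CH6824025 22, 17 passed. Antigen presentation by class II molecules was lower (camera adjusted p = 1.66e-05; adjusted p = 0.101 with an estimated correlation), with all 11 members below 0 and 2 adjusted over the list alone. It took 0.457% ± 0.0415 of UMIs in vehicle (SD, n = 3), 0.316% ± 0.0541 in CH6824025 (n = 4) and 0.0973% in sham. Of its members, 7 fell in the 5-section fit over all genes and 11 adjusted over the list alone, among them the class II chains H2-Eb1 (-0.74) and H2-Aa (-0.68) and the dendritic cell receptors Cd209a (-1.50) and Clec9a (-1.23). The interferon response was lower (2.57e-05; adjusted p = 0.101 with an estimated correlation), with 15 of 18 members below 0. Among its members, 5 fell in the 5-section fit over all genes, among them Irf9 (-0.38), Gbp2 (-0.54), Oasl2 (-0.80) and Gbp3 (-0.53), and 11 adjusted over the list alone.

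Interstitial matrix and myofibroblast genes were lower (camera adjusted p = 6.15e-05; adjusted p = 0.143 with an estimated correlation), with 30 of 38 members below 0. They took 1.25% ± 0.140 of UMIs in vehicle, 0.932% ± 0.0991 in CH6824025 and 0.234% in sham. Of these, 9 fell in the 5-section fit over all genes and 17 adjusted over the list alone, among them the fibroblast receptor Pdgfra (169 ± 0.733 to 100.4 ± 6.89 CPM), Spon1 (-1.03), the smooth muscle protein Tagln (-0.57) and the collagen cross-linking enzyme Loxl2 (-0.81). Col1a1 and Col3a1 were at -0.17 ± 0.20 and -0.71 ± 0.18 there, with edgeR adjusted p of 0.624 and 0.0535. TGF-beta signalling was lower (0.045; adjusted p = 0.271 with an estimated correlation), with 14 of 18 members below 0, and in the 5-section fit Thbs1 fell by 0.46 and Ltbp2 by 0.96, while 1 member fell with cluster 6 also left out. Basement membrane passed in the 5-section fit (adjusted p = 6.89e-05, and 0.664 with an estimated correlation), with Hspg2, Col4a3, Lama2 and Lama4 at -0.53, -0.45, -0.43 and -0.55, and not in the 7 sections (0.0548).

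Proximal tubule markers were higher (camera adjusted p = 2.57e-05; adjusted p = 0.0644 with an estimated correlation), with 23 of 25 members above 0, as were thick ascending limb markers (2.57e-05; adjusted p = 0.0644 with an estimated correlation), with all 12 above 0. Proximal tubule members rose in 9 cases in the 5-section fit over all genes and 18 adjusted over the list alone, among them the sodium-dicarboxylate transporter Slc13a3 (0.74), the endocytic receptor megalin, Lrp2 (0.59), and myo-inositol oxygenase, Miox (993 ± 118 to 1653 ± 159 CPM). In the thick ascending limb list Sostdc1 rose by 0.89 and the potassium channel gene Kcnj1 by 0.40. NRF2 and antioxidant genes (6.15e-05; adjusted p = 0.101 with an estimated correlation; all 13 above 0) and distal convoluted tubule markers (0.000411; adjusted p = 0.101 with an estimated correlation; 8 of 10 above 0) were higher, and in the 5-section fit Osgin1 rose by 0.59, Gclm, of glutathione synthesis, by 0.45, and the calcium channel gene Trpv5 by 0.82. Fatty acid oxidation (0.000673; adjusted p = 0.101 with an estimated correlation; 21 of 22 above 0) and oxidative phosphorylation (0.00195; adjusted p = 0.149 with an estimated correlation; all 19 above 0) were higher. By share of UMIs, fatty acid oxidation took 0.514% ± 0.0283 in vehicle and 0.547% ± 0.0544 in CH6824025 (exact permutation p = 0.4). Oxidative phosphorylation took 0.698% ± 0.0452 and 0.843% ± 0.0848 (exact permutation p = 0.114). The exact permutation p was 0.286 for NRF2 genes and 0.114 for proximal tubule and for thick ascending limb markers. Of the oxidation genes, 3 rose in the 5-section fit over all genes, namely Acadvl (0.39), Cpt2 (0.31) and Ehhadh (0.59). Adjusted over the list alone, 14 rose in that fit. There 14 respiratory chain genes rose over all genes and all 19 adjusted over the list alone, among them Cyc1 (447 ± 12.9 to 582 ± 15.4 CPM) and Atp5c1 (0.39). With the spots of panel cluster 6 also left out, 7 respiratory chain genes, 1 oxidation gene and 5 proximal tubule members rose over all genes, and 19, 6 and 11 adjusted over the list alone.

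B and plasma cell markers were lower in the 7 sections (camera adjusted p = 0.0116; adjusted p = 0.113 with an estimated correlation) and not in the 5-section fit (0.106). Other lists did not pass in the 7 sections. They were chemokines and cytokines, collagen receptors, macrophage, T and NK cell, neutrophil, complement, tubule injury, cell cycle, immediate early genes, xenobiotic metabolism, principal, intercalated, inner medulla, urothelium, podocyte, endothelium, smooth muscle and adipocyte, with adjusted p from 0.0563 to 0.949. In the 5-section fit xenobiotic metabolism (0.00706), intercalated cell (0.0322), neutrophil (0.0473) and erythroid markers (0.0256) were higher, and T and NK cell (0.0325) and endothelium markers (0.0236) lower. Estimated correlations gave adjusted p from 0.627 to 0.973 over all lists of that fit. S100a9, a neutrophil protein, rose by 1.45 there, Cyp4a10 by 1.12 and Ugt1a2 by 1.27, and the endothelial genes Pecam1 and Cdh5 fell by 0.54 and 0.57. Erythroid genes took 0.0287% ± 0.0104 of UMIs in vehicle and 0.0536% ± 0.0253 in CH6824025 (exact permutation p = 0.171). Skeletal muscle and adrenal cortex shares gave exact permutation p of 0.571 and 0.514. The smallest p this test allows, 0.0571, was reached by the shares of matrix, collagen receptor, TGF-beta, class II, interferon, distal convoluted tubule and endothelium genes, with an adjusted p of 0.269 over the 33 lists.

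**Figure D2:**
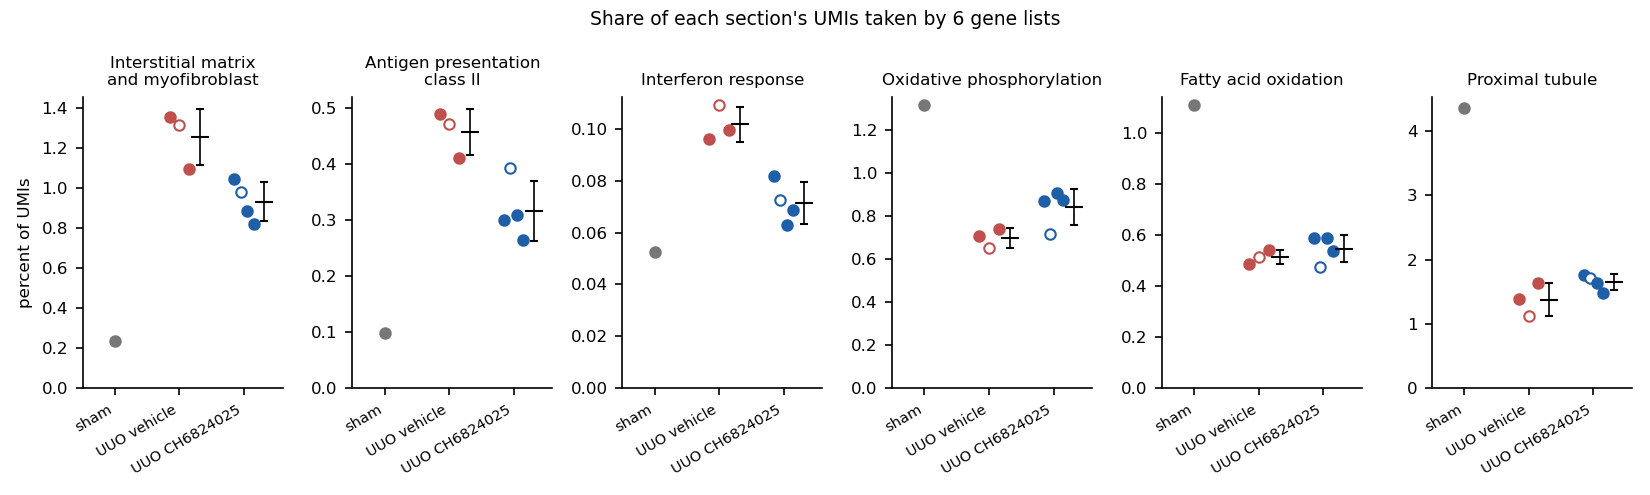
Percent of UMIs taken by 6 gene lists (y axis) in each section by group, with bars for mean ± SD over the sections of a group and open circles for vehicle 18 and CH6824025 22. Interstitial matrix averages 1.25% in vehicle and 0.932% in CH6824025 sections.

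A further comparison asked whether genes that obstruction changed moved back with CH6824025. Of 51 genes raised by UUO, 31 were lower with CH6824025 than with vehicle (60.8%, 95% Clopper-Pearson interval 46.1% to 74.2%), and of 15 genes lowered by UUO, 13 were higher (86.7%, 59.5% to 98.3%). Simulations with no treatment effect and the same vehicle libraries gave 58.4% ± 21.0 and 81.4% ± 13.2, so these shares lay within 1 SD of those from shared controls. In the fits without vehicle 18 and CH6824025 22, 3216 of 4327 raised genes (74.3%) were lower with CH6824025 and 3173 of 3901 lowered genes (81.3%) were higher, against 54.8% ± 0.759 and 55.6% ± 0.679 in 40 simulations. Of the 589 genes that fell with CH6824025 there, 461 had risen with UUO where 164 would be shared by independent lists, and of the 698 that rose, 566 had fallen with UUO where 175 would be shared. Only 11 genes fell in both comparisons and 51 rose in both, against 147 and 195. Both comparisons use the same vehicle sections, and the expected overlaps do not take this into account. The simulations did, but they drew each gene independently, so their SD leaves out differences that many genes share between sections. The gap between the shares and the simulations is therefore no measure of an effect of treatment. Without CH6824025 22 alone the shares were 77.2% and 84.4%, a setting for which no simulation was run.

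Regions of the kidney were compared next. The main clustering gave 24 clusters, 9 of them with over 90% of their spots from 1 section, which held 90.7% of the spots of CH6824025 22 and 54.0% of those of vehicle 18. Proximal tubule clusters held 17.7%, 0.186% and 24.7% of spots in vehicle 16, 18 and 19 and 17.8%, 42.5%, 21.6% and 17.3% in CH6824025 21 to 24. Distal convoluted tubule clusters held 11.7%, 0.0465% and 0.488% against 12.2%, 0.721%, 14.4% and 14.4%. None of the 4 shares compared, which also included urothelium and glomerulus, passed (smallest exact permutation p = 0.114, adjusted 0.457), and this test allows no p under 0.0571 with 3 against 4 sections.

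Clusters from the marker panel, chosen after seeing the data, each held spots of all 7 UUO sections and took their names from the marker lists, with inner medulla (cluster 0), proximal tubule (clusters 1 and 2), intercalated cell (3), distal convoluted tubule (5), glomerulus (7), principal cell (8) and urothelium (9) clusters and unnamed clusters 4 and 6. Cluster 6 made up 5.07%, 14.6% and 13.9% of spots in the vehicle sections and 0.296%, 0.135%, 0.0862% and 0.165% in the CH6824025 sections (exact permutation p = 0.0571, adjusted 0.327, the smallest p this test allows). Its spots lay together in the vehicle sections, where 3.54 to 5.19 of the 6 neighbours of a spot were also in cluster 6, and apart in the CH6824025 sections, where this mean was 0. Median UMIs of its spots were 45916, 18817.5 and 25229 in vehicle 16, 18 and 19, against 46470.5, 38495 and 39340.5 over all spots of these sections. Tissue images were not used here, so whether cluster 6 is normal anatomy reached by the plane of the section was not determined. At a resolution of 0.3 it did not form a cluster of its own, and the inner medulla cluster held 34.6% ± 5.77 of spots in vehicle and 20.4% ± 3.70 in CH6824025 sections (exact permutation p = 0.0571, adjusted 0.114).

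**Figure D3:**
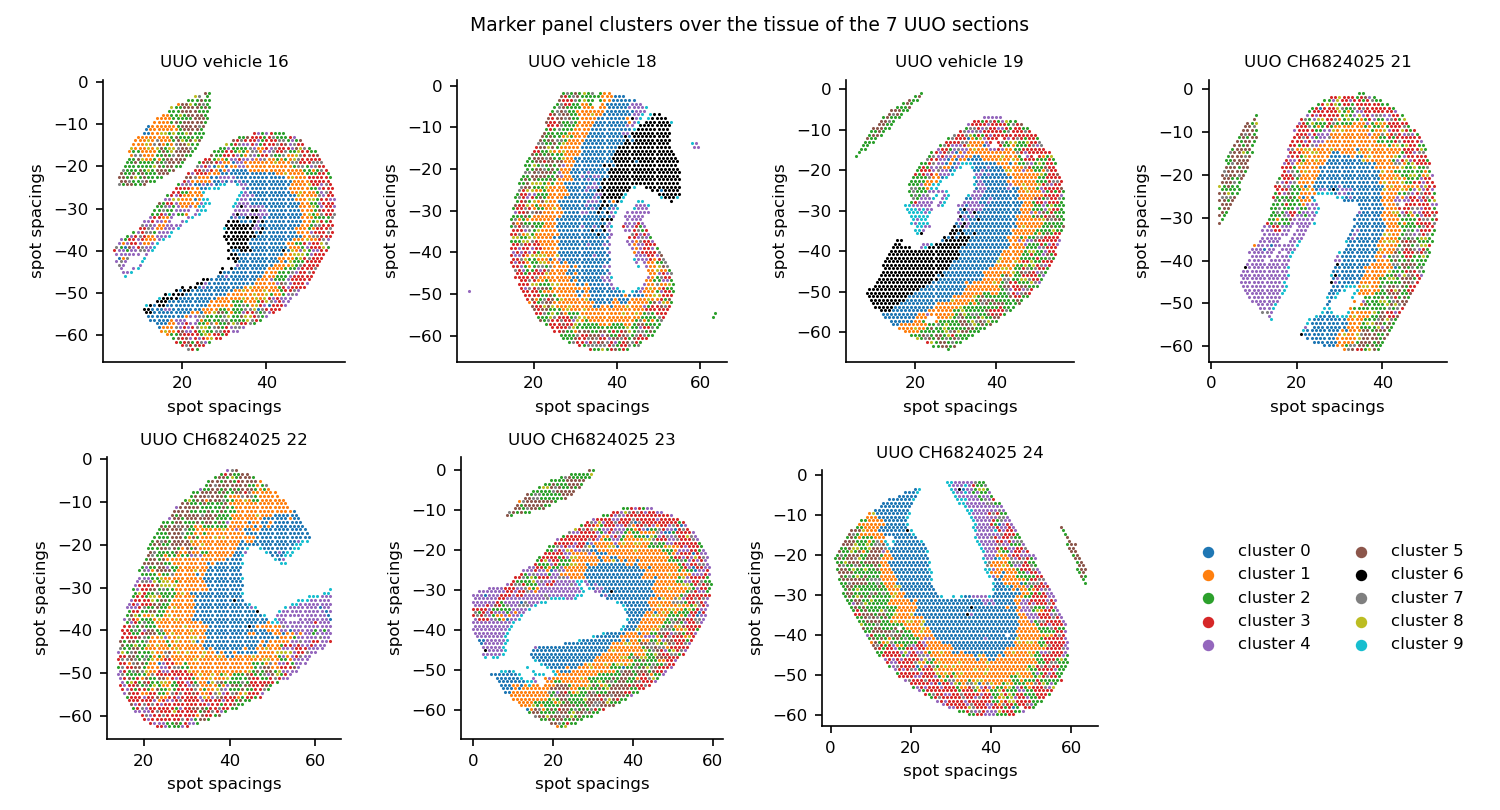
Positions of spots on the array (axes in spot spacings) in the 7 UUO sections, colored by marker panel cluster, with cluster 6 in black. Cluster 6 forms an area in each vehicle section and covers at most 0.296% of spots in a CH6824025 section.

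Within regions, the question was whether genes differed at a given place rather than through the mix of places. In the main clustering only the glomerulus had at least 50 spots in every section, and 0 of 12475 genes passed there with edgeR, with 321 at an unadjusted p under 0.05; without CH6824025 22, 1 gene passed. In the 8 panel clusters tested over 7 sections 0 genes passed in each with edgeR, with 234 to 670 at an unadjusted p under 0.05. Without vehicle 18 and CH6824025 22, Cyp4a14 rose in all 8 clusters, by 1.31 to 2.15 on the log2 scale, and H2-Eb1 fell in all 8, by values between -1.12 and -0.65. Fbn2 was lower in all 8 and past the threshold in 7, from -3.37 to -0.99. Col3a1 passed in 7 clusters as lower (-1.01 to -0.06 over all 8), Pdgfra in 6 and Col1a1 in 5, with 1 cluster of the 8 at 0.59. The peroxisomal enzyme gene Acaa1b and the scaffold gene Pdzk1 rose in 7 clusters. Ddr1 lay between 0.05 and 0.25 and Ddr2 between -0.53 and -0.08, past the threshold in 0 of 8. The genes summarised over the 8 clusters, other than Ddr1 and Ddr2, were chosen after their values were seen.

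The 5-section fits called 1090 genes in the inner medulla cluster, from which cluster 6, found mostly in vehicle sections, was separate at this resolution, 355 and 535 in the proximal tubule clusters, 1024 in the intercalated cell cluster, 16 in cluster 4, 246 in the distal convoluted tubule, 253 in the glomerulus and 236 in the principal cell cluster. In the inner medulla cluster Igfbp2, which binds insulin-like growth factors, fell by 3.26 and the adenylate kinase gene Ak4 rose by 1.02. Igfbp2 was also among the leading genes of cluster 6. In proximal tubule cluster 1 the matrix genes Loxl2 and Dpt fell by 0.80 and 1.08, and in cluster 2 Slco1a1 and the mesenchymal cadherin gene Cdh11 fell by 2.03 and 1.06. Sprr2f, a small proline-rich protein gene of stressed epithelium, was among the leading rises in clusters 0, 1, 2, 3 and 8, by 1.09 to 2.25. In the distal convoluted tubule the injury marker Lcn2 and the fibrinogen gene Fgg fell by 1.12 and 2.05. In the glomerulus the chemokine gene Ccl5 fell by 1.54, the dendritic cell gene Cd209a by 2.03 and the lectin gene Mgl2 by 1.80. Many of these genes were not particular to the cluster named. Mgl2 passed as lower in all 8 clusters tested, Cd209a, Cdh11 and Loxl2 in 7, and Ccl5, Slco1a1 and Igfbp2 in 6. Lcn2 passed in 3, and Ak4, Dpt and Fgg in fewer than 6.

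Matrix members had a median log2 fold change of -0.59 to -0.36 in 7 of these clusters and passed there, and in cluster 4, the unnamed cluster, the median was 0.00 (camera adjusted p = 0.332). Class II members (-0.97 to -0.53) and interferon members (-0.68 to -0.27) were lower, and oxidative phosphorylation (0.15 to 0.48) and fatty acid oxidation members (0.11 to 0.36) higher, in all 8. None of these list calls held with an estimated correlation, where their adjusted p ranged from 0.273 to 0.692.

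**Figure D4:**
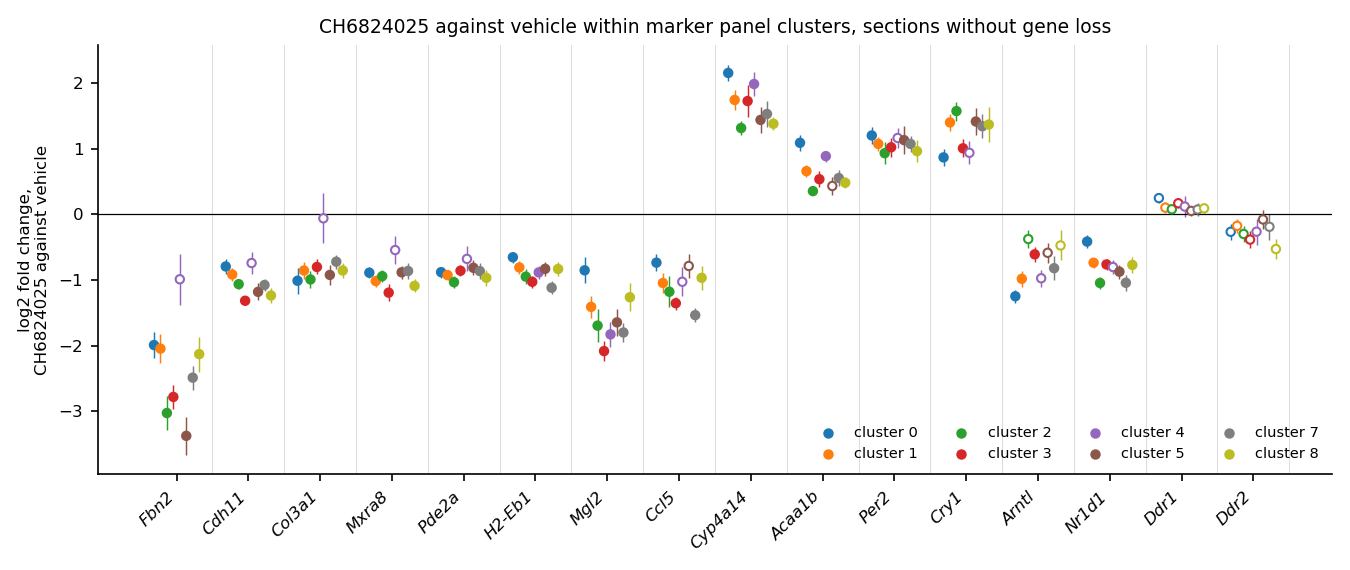
Log2 fold change of CH6824025 against vehicle ± SE (y axis) for 16 genes (x axis) in 8 marker panel clusters (colors), from 5 sections, with filled points for edgeR adjusted p under 0.05. Cyp4a14 lies between 1.31 and 2.15 in all 8 clusters and Ddr1 between 0.05 and 0.25.

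Whether the treatment difference itself differed between regions was tested as an interaction within sections. Between proximal and distal convoluted tubule, 6 of 13968 genes passed, 4 higher and 2 lower. All 6 had been among the genes that defined the clusters, and vehicle 18 had few spots in these regions, so they are not listed as findings. The count ranged from 1 to 111, for leaving out vehicle 18 or CH6824025 21 and CH6824025 22, with 101 without vehicle 16, 2 without vehicle 19, 32 without CH6824025 23 and 11 without CH6824025 24. Between the inner medulla and proximal tubule panel clusters in 5 sections, 498 of 14423 genes passed, 39 higher and 459 lower in the proximal tubule minus inner medulla difference. The inner medulla cluster does not hold the spots of cluster 6, which made up 5.07% to 14.6% of the vehicle sections, and the interaction was not tested with both clusters joined. The matricellular gene Ccn1 (0.63), Lcn2 (0.52), Anxa1 (0.44) and Igfbp3 (0.79) led the higher ones. Sprr1a (-1.15), the metalloprotease gene Mep1b (-0.91), the transporter gene Slc22a19 (-1.02) and the ketone body enzyme gene Bdh1 (-0.87) led the lower ones. Fatty acid oxidation members had a median of 0.36 in the inner medulla cluster and 0.20 in proximal tubule cluster 1. The mix of cells within the spots of these clusters was not tested. A group difference in that mix was therefore not separated from a treatment difference between places.

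Since DDR1 is the named target, the lists that share spots with Ddr1 were compared. Nearly every spot carried the transcript, so the planned split left 9 to 34 spots without Ddr1 per UUO section, and 98.4% to 99.2% of thinned spots had it, against 94.1% in sham. With this split 0 of 33 lists passed the exact sign-flip test, 16 having an unadjusted p under 0.05. Split at the section median of Ddr1 UMIs, chosen after seeing the data, 22 lists passed, 13 of them higher where Ddr1 was higher. Intercalated cell (0.41 ± 0.08, SD over 7 sections), principal cell (0.34 ± 0.10), tubule injury (0.34 ± 0.09), distal convoluted tubule (0.33 ± 0.09) and chemokine lists (0.33 ± 0.08) were higher in all 7 sections, and urothelium (-1.01 ± 0.60), proximal tubule (-0.47 ± 0.15) and interstitial matrix (-0.37 ± 0.16) lower in all 7, each with an exact sign-flip p of 0.0156 (adjusted 0.0271). Within panel clusters 11 lists passed, 6 of them higher, with chemokines at 0.29 ± 0.06, tubule injury at 0.28 ± 0.05, complement at 0.14 ± 0.05 and class II at 0.13 ± 0.06, and matrix at -0.21 ± 0.08 and smooth muscle at -0.19 ± 0.15 (exact sign-flip p = 0.0156, adjusted 0.0469). Spp1 is in both the chemokine and the tubule injury list and, at 27646 CPM in UUO vehicle, gives most of the UMIs of each, so their ratios are not independent. For a difference of these ratios between vehicle and CH6824025 sections the smallest adjusted exact permutation p was 0.629 for the median split and 0.973 within panel clusters. This test cannot go below an unadjusted 0.0571 with 3 against 4 sections, and no other test of the difference was run.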

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

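The tests of region makeup for the clock genes and of proximal tubule for the matrix genes, and the counts of other splits for the 7-section gene calls and for the 5-section fit were chosen after their results were seen; the other tests in this part were set down before.

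Among the CH6824025 sections, 1 section lay apart from the other 3 in 6 of 66 values tested, each time animal 22. By chance 3.3 would be reached by any of these sections, not by a given one. The values are related to each other, and the reference for lost genes left animal 22 out. Animal 22 had 15829 detected genes against 18433 to 18668, and 20.2% of genes lost against 0% to 0.00953%. Basement membrane genes took 0.375% of its UMIs against 0.270% to 0.284%, and inner medulla genes 0.355% against 0.177% to 0.197%. In the main clustering, distal convoluted tubule clusters held 0.721% of its spots against 12.2% to 14.4%, and proximal tubule clusters 42.5% against 17.3% to 21.6%. Clusters with over 90% of their spots from 1 section held 90.7% of its spots there. In the marker panel the distal convoluted tubule cluster held 9.83% of its spots against 5.29% to 7.46%. Proximal tubule clusters 1 and 2 held 26.4% and 14.5%, against 18.3% to 20.9% and 14.1% to 15.6%. Distal convoluted tubule genes took 0.182% of its UMIs against 0.120% to 0.156%. The test of a different treatment difference between regions was passed by 6 genes for proximal against distal convoluted tubule, which are not taken as findings since 1 gene was left without vehicle 18 or without CH6824025 21, and by 498 genes for proximal tubule against inner medulla panel clusters in 5 sections.

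The first pattern weighed is the loss of a shared set of genes from CH6824025 22 and vehicle 18. Lower depth is argued against, since CH6824025 21 drawn down to the total of CH6824025 22 lost 0% of genes. Region makeup is argued against for CH6824025 22, which lost at least 18.2% of genes within every panel cluster tested, while vehicle 18 lost 1.49% to 4.85% within them, for which no bound had been set. Treatment is argued against, since the lost genes had a median log2 difference of -0.11 between the other CH6824025 sections and vehicle 16 and 19, and vehicle 18 shared 296 of them. A fault of probe hybridisation or ligation in these sections may be the source and stays open, as untested.

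The second pattern is lower matrix and higher fatty acid oxidation genes with CH6824025. The tissue area of cluster 6, seen in vehicle sections, is argued against as the whole source, since the matrix members kept a median log2 fold change of -0.34 (bootstrap SE 0.0719, 38 members) with that area left out. The bootstrap drew list members and not sections, so this SE and those below leave out the variation between animals. A larger share of proximal tubule spots in the CH6824025 sections is argued against as the whole source for the matrix genes. Their medians were -0.52 and -0.59 (bootstrap SE 0.0567 and 0.0472) within the proximal tubule clusters. The mix of cells within the spots of a cluster was not tested and stays open as a source. The larger share of proximal tubule spots stays open for the oxidation genes. The median of the oxidation members was 0.11 (bootstrap SE 0.0654) within 1 proximal tubule cluster and 0.20 (SE 0.0401) within the other. An effect of CH6824025 on the obstructed kidney may also account for the pattern, as a hypothesis, and it rests on 2 vehicle and 3 CH6824025 sections at the gene level.

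The third pattern is the difference of circadian clock genes in the 5-section fit. Region makeup is argued against, since Arntl, Nr1d1, Per2 and Cry1 each kept their direction in 8 of 8 panel clusters. For a later time of day of sampling in the CH6824025 mice, a separate list of 9 clock genes was set beforehand to argue for it with at least 8 and against it with 6 or fewer going the way it predicts. The count was 6 of 8 measured, of which 3 passed the gene test, so with the gene not measured it is 6 or 7 and does not argue for time of day. That the unmeasured gene leaves the question open was settled after the count was seen, and sampling times are not given in the sources used here, so time of day and treatment cannot be told apart.

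Other splits of the sections were counted for each model of many genes. For the 7-section gene calls (edgeR; 556 at an unadjusted p under 0.05, DESeq2 48) and within the glomerulus (edgeR; 321 unadjusted) the real count and the highest other were 0, so 35 of 35 splits give as many by construction and decide nothing. With quality weights 6 of 35 splits gave at least the real 1377 genes, so chance was not excluded; the highest gave 9297, and the 5 larger splits put vehicle 18 and CH6824025 22 in the same set, which points to a structure of the samples. For the gene lists 3 of 35 splits gave at least the real 11 (highest other 14), and for the interaction of region and treatment 4 of 35 gave at least the real 6 (highest other 64, which again points to a structure of the samples), so chance was not excluded for either. For the 5-section fit the 10 splits are too few for a share under 0.05; 1 of 10, the real split, gave 1287 genes, and the highest other gave 0.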

How the results depend on the processing

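Tests without vehicle 18 and CH6824025 22, with quality weights, with cluster 6 left out, on the marker panel and on the Ddr1 median were chosen after seeing the data; the cause of a change was not tested unless stated. No paired analysis was possible because animal numbers are not shared between groups. Genes of CH6824025 against vehicle numbered 0 with edgeR under each setting fixed beforehand and 48 with DESeq2, 1287 in the 5-section fit, 1377 with quality weights and 856 with cluster 6 also left out. Genes of UUO vehicle against sham numbered 1337 with DESeq2, 35 without a filter on low counts, 8228 in the 6-section fit, 3701 with quality weights, and 0 to 4231 with 1 UUO section left out. Lists of CH6824025 against vehicle numbered 0 with an estimated correlation, 0 with fry, 17 in the 5-section fit (0 with an estimated correlation, 3 with fry) and 9 to 17 with 1 section left out; those of UUO vehicle against sham numbered 14 with an estimated correlation and 0 with it in the 6-section fit. Within regions, panel clusters in 5 sections gave 1090, 355, 535, 1024, 16, 246, 253 and 236 genes, and leaving out 1 section gave 0 to 1 in the glomerulus. The interaction gave 15 genes with RLE, 84 without a filter, 315 and 498 with panel clusters in 7 and 5 sections, and 1 to 111 with 1 section left out. Lists by Ddr1 numbered 22 at the median split and 11 within clusters. Of genes raised by UUO, 77.2% were lower with CH6824025 without CH6824025 22 and 74.3% without both sections; leaving out another UUO section left no called genes. Ddr2 reversed to 0.27 without vehicle 16, 0.07 without vehicle 19 and 0.20 without CH6824025 22, in a range from -0.61 to 0.27 with 1 section left out. Other values of named genes of CH6824025 against vehicle were the same in 431 cases and stronger in 87, and of UUO vehicle against sham the same in 216, stronger in 2 and weaker in 142. Not run were a resolution of 0.4 and no centring for genes within regions, region classes for Ddr1, and a block for the image scale, which only vehicle 16 did not share. Depth limits a gene at 0 to at most 0.0193 to 0.0448 CPM.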

Other observations

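The clock gene tests other than those on the separate list, and the cluster 6 values in this part, were chosen after seeing the data. Several genes of the circadian clock differed between CH6824025 and vehicle in the 5-section fit, in both directions. Arntl, which encodes BMAL1, fell from 22.9 ± 0.391 CPM in vehicle (SD, n = 2) to 11.8 ± 0.967 in CH6824025 (n = 3), and Nr1d1, which encodes REV-ERB alpha, fell by 0.76 on the log2 scale. Per2 rose from 33.3 ± 4.30 to 65.2 ± 7.38 CPM and Cry1 by 1.04. In a separate list of clock genes Npas2 fell by 0.62, Per3 rose by 0.58 and Tef by 0.45, while Per1 (0.64), Clock (-0.09), Bhlhe41 (0.26), Nfil3 (0.52) and Nr1d2 (0.18) did not pass. Dbp, outside that list, was at 0.16 (edgeR adjusted p = 0.143). Past the threshold within panel clusters, Per2 and Cry1 rose and Nr1d1 fell in 7 of 8 each and Arntl fell in 4 of 8.

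Other genes outside the naming rule, chosen after their values were seen, included Gpnmb, a transmembrane glycoprotein of lysosome-rich macrophages, which was at 4.31, 1.70 and 3.65 CPM in vehicle 16, 18 and 19 and 32.3, 1.04, 38.9 and 17.5 CPM in CH6824025 21 to 24, and 0.915 CPM in sham. Its log2 fold change in the 5-section fit was 2.98 ± 0.34 (edgeR adjusted p = 0.0119), and it rose in all 8 panel clusters tested. The chemokine receptor gene Ccr2 fell by 0.93 and the macrophage lectin gene Mgl2 by 1.38 there, C3 rose by 0.82, and Havcr1 was at 0.12 (adjusted p = 0.774). The injury marker Lcn2 was at -1.01 ± 0.16 (edgeR adjusted p = 0.0202) and, with cluster 6 also left out, at -0.70 ± 0.16 (adjusted p = 0.0513). Lcn2 ranged from -1.26 to 0.24 within panel clusters, lower past the threshold in 3 of 8.

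Whether cluster 6 is normal anatomy reached by the plane of the section was not determined. It held 100, 314 and 285 spots in vehicle 16, 18 and 19 and 6, 3, 2 and 4 in CH6824025 21 to 24. Igfbp2, Fcgbp and Aldh1a3 were among its leading genes outside the marker panel. Over whole sections Igfbp2 was at 109, 211 and 177 CPM in the vehicle sections, 12.7, 31.9, 36.8 and 17.5 CPM in the CH6824025 sections and 43.9 CPM in sham. Fcgbp, a mucin-like gene, was at 2.14, 8.60 and 9.35 CPM, then 0.377, 0.358, 0.217 and 0.617 CPM, with 7.48 CPM in sham. Aldh1a3, of retinoic acid synthesis, was at 2.45, 49.1 and 21.9 CPM in the vehicle sections and 2.27 to 7.85 CPM in the CH6824025 sections.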
